A study of Oryza sativa with 3 samples.

How the data were processed

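Total RNA from panicles was labelled with Cy3 or Cy5 and hybridised in pairs to 3 two-colour Agilent arrays, per the labels. Each array holds a knockdown pool and the wild type pool. The first array and its dye swap carry the same 2 RNAs and were counted as 1 replicate, and the array of the second knockdown pool is the other. The wild type RNA was 1 pool on all arrays, so it served as a single control sample, and the log ratio was tested against 0, which leaves out the control's own spread. The log ratio pairs the 2 channels of an array, but no independent wild type sample was paired with each knockdown pool.

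The array files deposited by the authors hold, per the file headers, the median signal intensity of each spot in both channels, the authors' normalized intensity per channel and the authors' ratio of knockdown over wild type. Agilent Feature Extraction is named in the submitters' processing notes, without a version. The method behind the normalized intensities is not given in the sources used here. The median intensities had no background taken off, as their values show. The ratio deposited by the authors equals the ratio of their normalized intensities within 1% for 100% of the values above the floor of 0.01. Those ratios were not centred, with log2 medians per array of -0.15, -0.21 and -0.18. The authors gave an absent flag to 2074, 2890 and 2413 probes on the arrays, which then have no ratio. The deposited table of the whole series has 19896 rows without probe names, and 100% of its rows were found among the ratios in the array files. Its column medians lay between 0.865 and 0.901. Its scale and direction were therefore taken from the array files, and those ratios served as an alternative.

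The median signal intensities were corrected with limma's normexp method at an offset of 50 and normalized within each array by loess. The plan had named mean signals against a background column. The columns used hold median signals and no background, so normexp was fitted to the median signals alone. Ratios of the dye-swapped array were turned so that every value is knockdown over wild type. A threshold for signal above background was set for each array and channel at the median plus 2.6 SD (from the MAD, times 1.4826) of the probes the authors flagged absent. It lay between 79.6 and 102.1. A probe was tested if it exceeded this on all 3 arrays in the knockdown channel or on all 3 in the wild type channel, which kept 17544 probes and left out 3951. Spots with outlier flags could not be removed, since the columns used carry none. Signals at or above 65000 were seen for 13 to 24 probes per array and were kept.

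The array and its dye swap were averaged, and the 2 pool values were fitted against 0 with lmFit and plain eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes and a two-sided threshold of 0.05. The residual spread of each probe was moderated with a prior of 21.2 degrees of freedom. The p-values measure spread between the 2 knockdown pools and none among wild type panicles. With 2 pool values per probe, that prior sets most of each SE. An SE therefore mainly reflects the spread between the pools over all tested probes, and its median was 0.074. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, over the lists with 5 or more tested probes, with adjustment over those 20 of 22 lists. A bound ("at least N-fold") was given where a channel was not above background on any array. It sets the bright channel's mean against the higher of the dim probe's signal and the lowest signal above background, per channel after loess and Aquantile, and stays open to dye bias because pool B has no swap.

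Genes were named by a rule fixed before the data were examined. It takes OsMADS2, the 12 largest rises and 12 largest falls among described probes past the test with 1 direction on all arrays, up to 4 members with the lowest p of each list, and the MADS-box genes. Chosen after their values were seen were the glutathione S-transferases GSTF15 and GSTF14, the PGPD14 and photosystem II P680 probes, and the seed storage and RNA silencing members. So were the probes given beside a named probe of the same description, mostly because they disagree with it. Each probe has its own accession, and probes sharing a description were treated as separate. MADS-box descriptions were matched to gene synonyms of the rice assembly ASM3414082v1, which named 19 of 22 probes, and the others keep their array names. The files name no genome build, so no coordinates are given. The lists were matched on description text, and descriptions can be old.

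The steps were tested on simulated data for the comparison of knockdown with wild type, with 200 of 17544 probes changed. The test recovered 53.7% of changes of 0.5 on the log2 scale, 84.6% of changes of 1 and 98.5% of changes of 2, none with the wrong sign, and 3.66% of calls were false. The median estimated sizes were 0.34, 0.80 and 1.56, below the simulated ones. The simulated wild type had no deviation shared by all arrays, and far fewer probes were changed than were called in the data. The 3.66% therefore does not cover false calls that come from the single wild type pool. Alternatives covered the background step, the normalization, the filter on dim probes, a dye correction, the authors' ratios, the arrays and pools left out, the eBayes model and the list tests. Median-centred ratios of the authors, a wild type pool with the spread of the knockdown pools, and lists without ill-fitting members were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.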

Results

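Gene expression was measured in rice panicles in which OsMADS2 was knocked down by a double-stranded RNA construct (RNA interference), and in wild type panicles of the cultivar TP309. OsMADS2 encodes a MADS-box transcription factor of the PISTILLATA type, the class B floral organ identity genes that act in lodicules and stamens. The series is titled as a search for genes acting downstream of OsMADS2. Total RNA was hybridised to 3 two-colour Agilent arrays of 21495 probes, each matched to its own full-length cDNA accession. Knockdown pool A was hybridised in Cy5 against wild type in Cy3 and again with the dyes exchanged, and knockdown pool B was hybridised in Cy5 only. The labels describe 2 independent knockdown pools and a single wild type pool, so each value below rests on n = 2 pools and leaves out the spread of wild type panicles. Median spot signals ranged from 130 to 275.5 over the channels, against thresholds for signal above background of 79.6 to 102.1. Of the 21495 probes, 17544 were above that threshold on all 3 arrays in at least one of the RNA types and were tested. The small number of arrays limits the precision of every value.

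The knocked-down gene was examined first. The OsMADS2 probe (AK070894, described on the array as RMADS219) was slightly lower in the knockdown pools, with a log2 ratio of -0.23 (SE 0.077, n = 2 pools, limma adjusted p = 0.0093), which is 1.17-fold. In the reference table RMADS219 is a synonym of a single gene, which also carries the name OsMADS2, but OsMADS2 is listed as a synonym of the OsMADS18 gene too, whose own probe read 0.30. The log2 ratio was -0.20 on array A, -0.04 on its dye swap and -0.34 on array B. The SE above, like the others below, comes mostly from the spread over all tested probes, not from these values alone. In the ratios computed by the authors, which were not centred, the same probe read -0.56, -0.32 and -0.74 on the log2 scale. The difference did not pass the test with a dye coefficient (adjusted p = 0.053), without array A (0.13) or with median centring in place of loess (0.63). It also did not pass when the wild type pool was given the spread of the knockdown pools (0.13). Where the probe lies relative to the part of the gene used in the RNA interference construct is not given in the sources used here.

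Most tested probes differed between the knockdown and wild type pools. At an adjusted p under 0.05, 7466 of 17544 probes were higher and 6989 were lower in the knockdown pools, together 82.4% of those tested. Many differences were small, with a median absolute log2 change of 0.66 among the probes that passed. A change of 2-fold or more on every one of the 3 arrays was found for 2531 probes in the upward and 1546 probes in the downward direction. Of the probes past the test, 98.6% had the same direction on all 3 arrays, the dye swap included. The test takes no account of variation among wild type panicles, and with median centring in place of loess 3665 probes were lower instead of 6989. With offset 0 in the background step 2492 probes, and in the authors' ratios 3323, were at least 2-fold lower on all 3 arrays.

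The log ratios of pool A and pool B were correlated across the tested probes, with Pearson's r = 0.99 and Spearman's rho = 0.98, where probes are not independent replicates. Both pools share the wild type pool. With no effect at all, and the wild type pool assumed to have the same spread as the knockdown pools, the simulated r was 0.49. The covariance of the pools was 1.484 against a simulated 0.014. The spread of wild type cannot be measured from a single pool, and that pool could not be split. Part or all of the excess may therefore come from the wild type pool.

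**Figure D1:**
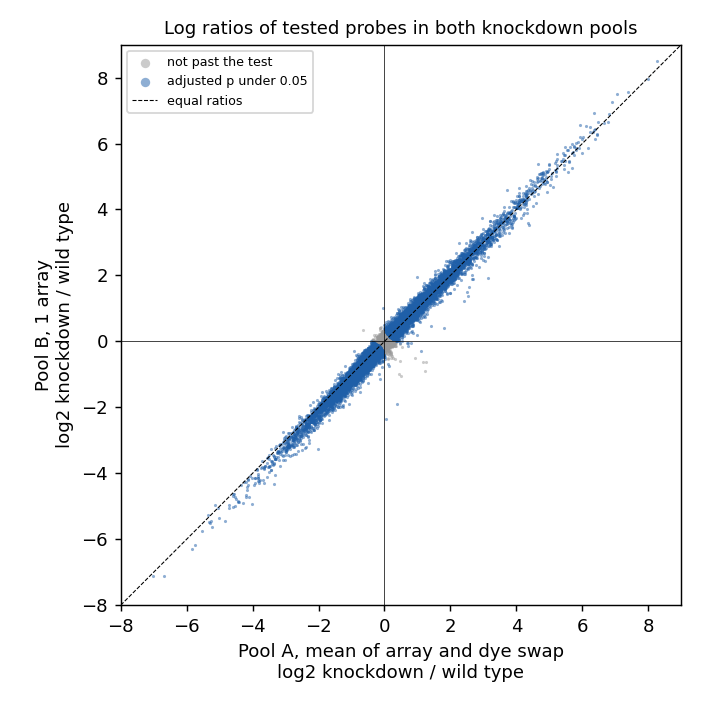
Log2 ratio of knockdown over wild type for the 17544 tested probes in pool A (x axis, mean of the array and its dye swap) and pool B (y axis, 1 array). Blue points passed the test at an adjusted p under 0.05, grey points did not, and the dashed line marks equal ratios; the points lie along it with r = 0.99.

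Of 22 MADS-box probes on the array, 20 were tested, and 13 were higher, 6 lower and 1 not different in the knockdown pools. The class B gene OsMADS16, the partner type of OsMADS2 in lodicules and stamens, rose 10.4-fold (log2 3.38, SE 0.077, limma adjusted p = 1.63e-21). OsMADS4, the other PISTILLATA-type gene, rose 1.67-fold (log2 0.74, SE 0.074). The SEPALLATA-type genes OsMADS8, OsMADS7 and OsMADS1 rose by 2.47, 1.83 and 1.80 on the log2 scale. Among the ovule-type genes, OsMADS13, above background in wild type on 2 of the 3 arrays, rose by 1.83, while OsMADS21 was not well above background in wild type and was at least 5.30-fold higher. The largest rise in the family belonged to an unnamed MADS-box protein (AK108568), at log2 5.17 (SE 0.074).

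In the opposite direction, RMADS221 fell to a log2 ratio of -1.94, the SEPALLATA-type gene OsMADS5 to -0.88, and OsMADS50, OsMADS55 and OsMADS14 to -0.55, -0.51 and -0.36. OsMADS26 read -0.07 (adjusted p = 0.36) and did not pass the test. OsMADS17, of the AGL6 type, passed with log2 0.69, but its ratios were 0.89 and 0.97 on the arrays with knockdown in Cy5 and -0.06 on the dye swap, and it did not pass without array A (log2 0.46, adjusted p = 0.059). With median centring in place of loess, FDRMADS5, OsMADS50, OsMADS14, OsMADS55 and OsMADS18 no longer passed, with unchanged directions. OsMADS18 also failed in the authors' ratios as deposited. There OsMADS26 passed as lower, which it did in 2 of 16 alternatives. As a list of 19 probes matched by description, which leaves out OsMADS13, the family did not stand apart from other genes (camera adjusted p = 0.14).

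**Figure D2:**
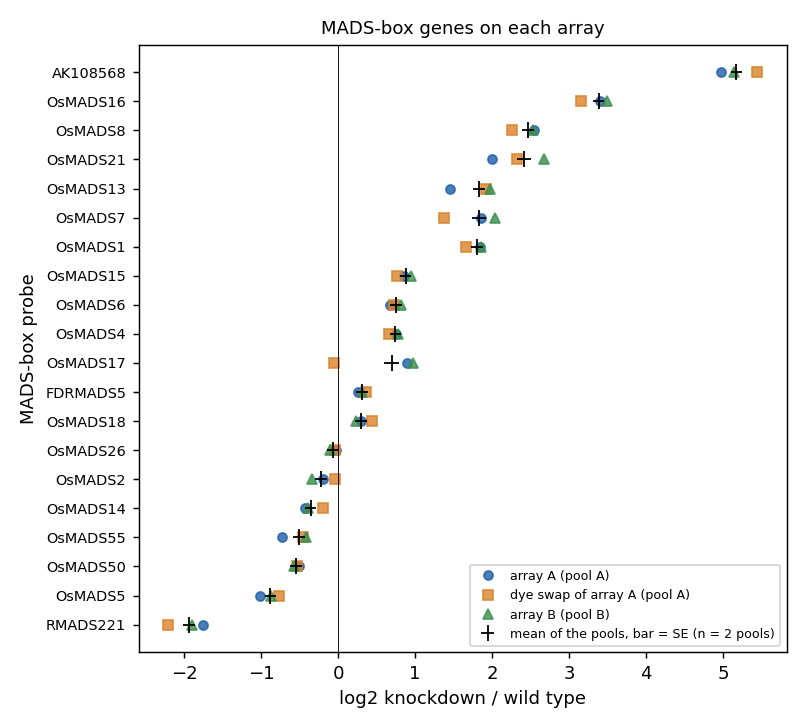
Log2 ratio of knockdown over wild type (x axis) for the 20 tested MADS-box probes (y axis), with 1 symbol per array and a black tick for the mean of the pools. The bar is the moderated SE (n = 2 pools), set mostly by the spread over all tested probes. OsMADS16 lies at 3.38 and OsMADS2 at -0.23, and OsMADS17 is the probe whose direction turns on the dye swap.

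Among probes with a functional description, the largest rise was that of a transcript with partial homology to Osc6, a gene expressed in the anther. It rose by log2 8.38 (SE 0.077), and chalcone synthase, the entry enzyme of flavonoid synthesis, by 7.98 (SE 0.073). Both were above background in wild type on 2 of the 3 arrays, so their sizes and ranks are uncertain, with log2 values over the alternatives from 8.07 to 10.31 and from 7.68 to 9.86. The next were an O-methyltransferase (ZRP4) at 7.48, a beta-expansin at 6.71, an RNase S-like protein at 6.65, a proline-rich protein at 6.42 and a cysteine protease at 6.37. The beta-expansin was above background in wild type on 1 of the 3 arrays, and its log2 value ranged from 6.36 to 9.17 over the alternatives. ZRP4 ranged from 7.24 to 8.78, the RNase S-like protein from 6.37 to 8.05 and the cysteine protease from 6.08 to 8.14. The order of these rises is therefore uncertain. Rubisco activase, which keeps the carbon-fixing enzyme active, rose by 6.35. Lipid transfer protein b1, a second beta-expansin, lipid transfer protein ltp2 and an HD-zip transcription factor rose by between 6.11 and 6.32. The second beta-expansin was above background in wild type on 2 of the 3 arrays and ranged from 5.96 to 7.91 over the alternatives. Probes of the same description disagreed, with log2 values of 1.90, 0.09 and -0.66 under the ltp2 name, 0.01 and -0.55 for HD-zip factors and -0.16 for the other putative beta-expansin.

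The largest fall was that of glutamate decarboxylase GAD3, which makes gamma-aminobutyrate. It fell by 6.89 on the log2 scale (SE 0.086). The zinc finger protein ZFP14, the water-stress protein WSI18 and the transcription factor WRKY09 fell, with log2 ratios of -5.44, -5.40 and -5.40. A phytochelatin synthetase, a stearoyl-acyl carrier protein desaturase and the early nodulin OsENOD93a fell, with ratios of -5.36, -5.19 and -5.06. An ethylene-responsive protein, a cytochrome P450, a CBF1-like protein, a heat shock protein and the trehalose-6-phosphate phosphatase OsTPP1 had log2 ratios from -4.84 to -4.60. The P450 description is shared by 16 other tested probes, of which 12 were higher. These are the 12 largest rises and 12 largest falls among described probes chosen for 1 direction on all 3 arrays.

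Genes of photosynthesis, fixed beforehand as markers of green tissue, were higher in the knockdown pools. Of 33 tested probes, 31 rose and 2 fell, with a median log2 ratio of 2.56 (camera adjusted p = 6.16e-09 with a preset correlation). The list did not pass with an estimated correlation, at an adjusted p = 0.59. With 2 pools that test had almost no power to pass any list, here or below. The Rubisco small subunit rose by 5.83, a photosystem II subunit by 5.55 and phosphoribulokinase by 5.34. Probes described as the photosystem II P680 apoprotein disagreed, with 2 higher and 2 lower.

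Genes of cell division were lower in the same pools. Of 39 probes for the cell cycle and DNA replication, 24 fell, 6 rose and 9 did not pass, with a median log2 ratio of -0.42 (camera adjusted p = 0.0046; adjusted p = 0.61 with an estimated correlation). Its adjusted p was 0.054 with fry. The log2 ratio was -3.17 for cyclin Ia, -3.06 for cyclin 2, -3.04 for a cdc2 kinase and -2.19 for cyclin CycB2;os;1. Of 8 probes for core histones, 6 fell and 2 did not pass, with a median of -1.40 (camera adjusted p = 0.0098; adjusted p = 0.59 with an estimated correlation). The log2 ratio was -3.19 for a histone H2A and -2.90 for a histone H4. In the authors' ratios the histone list no longer passed (adjusted p = 0.077).

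Genes of oxidative stress were mostly higher, with 49 of 71 probes up, 14 down and 8 not past the test, and a median of 0.67 (camera adjusted p = 0.00071; adjusted p = 0.59 with an estimated correlation). Catalase probes rose by 5.97 and 4.08, a peroxidase by 5.47 and a glutathione S-transferase by 3.68. The last pair were above background in wild type on 2 and 1 of the 3 arrays. Over the alternatives they ranged from 5.14 to 7.51 and from 3.35 to 5.66. Members moved both ways: glutathione S-transferases GSTF15 and GSTF14 fell, with log2 ratios of -2.77 and -2.72.

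The other 16 of the 20 lists with 5 or more probes did not pass as lists. Most of their members changed one by one, but so did 82.4% of all tested probes. With median centring in place of loess 6 of these lists also passed: cell wall, vascular and lignin, lipid transfer, anther, heat shock and defence genes. Water and ion transport, which includes the proton pumps that drive cell swelling, had 10 probes higher and 3 lower of 14 (median 0.72, adjusted p = 0.11), among them plasma membrane proton pumps at 2.83 and 2.46. Cell wall genes had 24 higher and 14 lower of 44 (median 0.46, adjusted p = 0.11). Among them were a cellulose synthase at 4.94 (other probes of that description at 3.87 and -0.01) and expansin Os-EXP-1 at 4.73. Vascular and lignin genes had 13 higher and 4 lower of 19 (adjusted p = 0.11), with cinnamyl alcohol dehydrogenase at 4.02 and phenylalanine ammonia-lyase at 3.75. Lipid transfer proteins had 8 higher and 3 lower of 13 (adjusted p = 0.11). Markers of anther, tapetum and pollen were divided, with 8 higher and 8 lower of 17 (median 0.15, adjusted p = 0.85). The mean of that list was 0.90. Chalcone synthase, named above, belongs to it too, at 7.98. An anther-specific protein rose by 4.85 and profilin A, above background in wild type on 2 of the 3 arrays, by 4.10. Anther-specific protein YY2, above background in wild type on 1 of the 3 arrays, rose by 2.82. In contrast, 4 probes for the pollen germination protein PGPD14 were lower. Of the 8 meristem and floral regulators, 5 were higher and 3 lower (adjusted p = 0.80), and the members with the lowest p went both ways: an Aintegumenta-like gene at -2.83, NAM proteins at -2.56 and 2.13, and the cell death-related protein SPL11 at 2.00. The median of that list was 0.44 and its mean -0.0017. Without ill-fitting members 6 of its probes remained, with a median of -0.16 (camera adjusted p = 0.79).

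Hormone lists were mixed. Cytokinin had 11 lower and 5 higher of 18 (median -0.43, adjusted p = 0.11), but the 4 members with the lowest p are not known from cytokinin signalling. They are the pseudo-response regulators OsPRR73, OsPRR37 and OsPRR95, known from the circadian clock, at -2.82, -1.80 and -1.45, and a pyrophosphate-dependent phosphofructokinase of sugar metabolism (AK060632) at -1.78. Ethylene and jasmonate had 18 lower and 10 higher of 29 (adjusted p = 0.13), with ethylene-forming oxidases going both ways, at -4.16 and at 3.86. Auxin had 7 higher and 7 lower of 17 (adjusted p = 0.92), with a median of -0.09 and a mean of 0.27. Gibberellin had 3 in each direction of 7 (adjusted p = 0.74). Its members with the lowest p were GIGR2 at -3.20, a locus weakly similar to mucin at 3.03, CIGR1 at -2.64 and a C-20 oxidase at 0.82. Without ill-fitting members 6 gibberellin probes remained, with a median of -0.22 (camera adjusted p = 0.30). The abscisic acid, LEA and dehydrin list had 5 higher and 3 lower of 9 (adjusted p = 0.51).

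Heat shock and chaperone genes had 22 lower and 11 higher of 37 (median -0.35, adjusted p = 0.11), and ribosomal protein genes 38 lower and 15 higher of 70 (adjusted p = 0.13). The ribosomal members with the lowest p were higher, among them the plastid proteins L31 at 2.51 and L11 at 1.80. Defence genes had 33 higher and 23 lower of 63 (adjusted p = 0.16), with probenazole-inducible PBZ1 at 5.70, chitinase IIb at 6.06 and WRKY09 at -5.40. Sugar and starch genes had 20 higher and 12 lower of 39 (adjusted p = 0.30), with OsTPP1 at -4.60 and granule-bound starch synthase at 3.57, the latter above background in wild type on 1 of the 3 arrays and ranging from 3.23 to 5.84 over the alternatives. Seed storage had 1 tested probe, lower, and RNA silencing had 2, with OsAGO1 at -1.11 and an Argonaute-related locus at 0.27. In each of the 20 lists the counts adjusted over the list alone were equal to those over all probes.

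**Figure D3:**
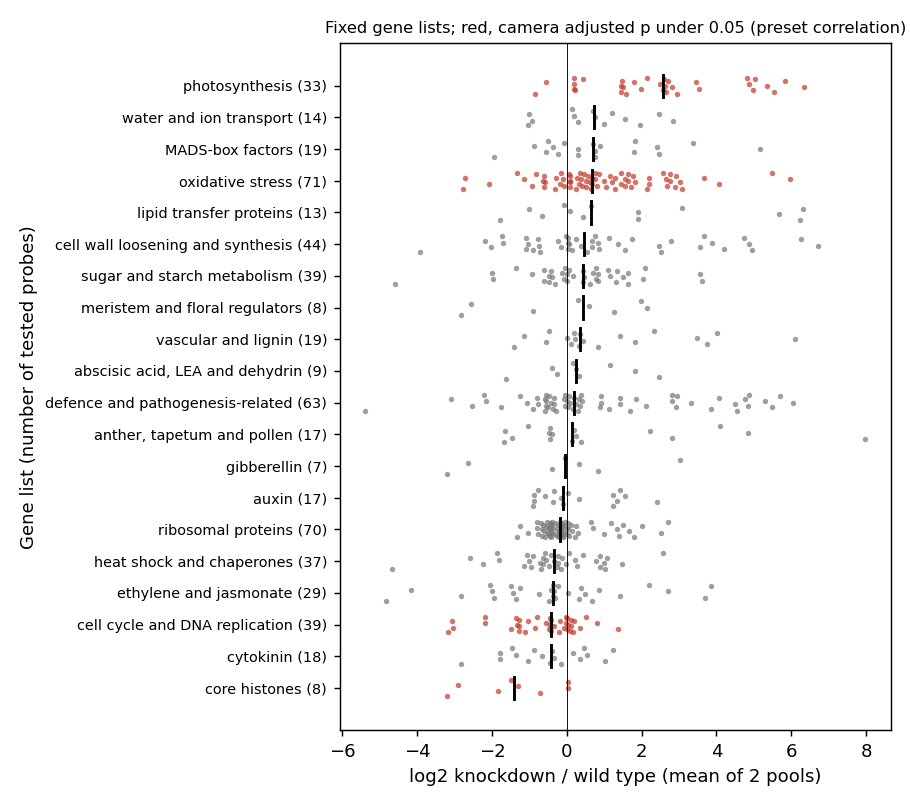
Log2 ratio of knockdown over wild type (x axis, mean of 2 pools) for each tested probe of the 20 gene lists (y axis, number of probes in brackets), with a black bar at the list median. The 4 lists in red had a camera adjusted p under 0.05 with the preset correlation, with medians of 2.56, 0.67, -0.42 and -1.40.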

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

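Tests with the authors' ratios after centring, with the wild type pool given the spread of the knockdown pools and with lists freed of ill-fitting members were chosen after seeing the data. The counts of higher and lower probes stayed within 1.5 times of 7466 and 6989 in every alternative run, except that median centring in place of loess gave 3665 lower probes; higher probes ranged from 5387 to 7696. With median centring the OsMADS2 ratio was -0.14 (adjusted p = 0.63), the correlation of the pools 0.965 and the number of lists past the threshold 10. OsMADS2 also lost its call without array A (-0.19), with a dye coefficient (-0.15) and with the wild type spread assumed (-0.23). It stayed below 0 in the 15 alternatives other than Aquantile normalization and passed in 9 of the 13 with a test, with adjusted p from 0.00082 to 0.63, and ranged from -0.34 to -0.12 when a pool was left out. Probes at least 2-fold lower on all 3 arrays numbered 2492 with offset 0, 3323 in the authors' ratios and 2759 in those ratios after centring. The pool correlation was 0.984 with offset 0 and 0.982 without array A. Of the lists, 0 passed camera with an estimated correlation, which with 2 pools had almost no power to pass any list. With fry, which does not compare a list with other genes, 14 passed. Cell cycle and DNA replication was not among these 14 (fry adjusted p = 0.054). With a pool left out, probes 2-fold higher ranged from 2576 to 2976 and 2-fold lower from 1569 to 2005. The cause of these changes was not tested. As deposited, the authors' ratios had a median of -0.17 over the tested probes against 0.02 here. Of 107 named probes past the test other than OsMADS2, 101 kept their call in every alternative that gave them a value. Apart from the MADS-box genes, the named probes were picked for large changes or low p, which favours keeping a call. The count therefore says little about the other probes. Aquantile normalization left the ratios as they were and so tests nothing. Agilent's own log ratios were not run, as the columns used hold none, and a random block for the pools could not be fitted, with 0 probes giving an estimate from 3 arrays. Dim probes limit the sizes: 818 tested probes were above background in knockdown and on no array in wild type, and 159 the other way.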

Other observations

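The lists of this part were chosen after the data were seen, as were the authors' centred ratios and the tests of dye bias, of the share of probes past the test under other settings, of stage, of handling and of the OsMADS2 probe. Genes of the circadian clock were lower in the knockdown pools on all 8 probes matched, with a median log2 ratio of -1.28. OsPRR1 read -1.03, the Gigantea-like gene -0.88 and the oscillator component COC1 -1.21. The OsPRR probes, with a pair each for OsPRR37 and OsPRR73, also belong to the cytokinin list of the report. The probes therefore stand for fewer genes. With a single wild type pool, an effect of the knockdown on these genes cannot be told apart from other differences between the pools. Probes for cytochrome P450 enzymes were mostly higher, 21 of 27 with 3 lower (median 0.78), and proteasome subunits mostly lower, 22 of 39 with 6 higher (median -0.25). With an estimated correlation none of these lists passed (adjusted p = 0.33 for clock and P450 genes and 0.49 for the proteasome). That test had almost no power to pass any list here.

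The share of tested probes past the test, 82.4%, is large. It was 68.9% with the wild type pool given the spread of the knockdown pools, which is an assumed spread. Dye bias is argued against by the swap, where 97.6% of the 14038 probes past the test on arrays A and B alone had the same direction, noise of dim probes by those above the 75th percentile of brightness, of which 85.1% passed, and the background step by a share of at least 80.4% without subtraction or with offset 0. Loess stays open: the share was 51.6% with median centring in its place against 81.9% in the authors' centred ratios, whose normalization is not given in the sources used here, and their same direction for 99.99% of the probes past the test does not bear on how many pass. The wild type pool may also differ from the knockdown pools in panicle stage or organ make-up. The median of the cell cycle and histone probes, at -0.45, and that of photosynthesis, at 2.56, go with older organs in the knockdown pools. The anther list decides nothing as a list, with a median of 0.15, a mean of 0.90 and 8 probes higher and 8 lower. Its members with the lowest p were higher, led by chalcone synthase at 7.98, while probes for PGPD14 were lower. With 1 wild type pool, stage and an effect of the knockdown cannot be told apart.

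Genes of stress and signalling responses were lower in the knockdown pools, 43 of 67 probes with 19 higher, at a median of -0.78 (adjusted p = 0.35 with an estimated correlation). MAP kinase 1 and OsNAC4 are among the lower ones, at -3.02 and -3.27. Their families went both ways, with a MAPK-like protein at 4.93 and OsNAC5 at 1.92. The list holds several of the largest falls already named, among them WSI18 and WRKY09, so its direction is not independent of them. Related lists fixed beforehand went different ways. Oxidative stress had 49 higher and 14 lower of 71, and defence 33 higher and 23 lower of 63. Heat shock had 22 lower and 11 higher of 37, and ethylene and jasmonate 18 lower and 10 higher of 29. A candidate explanation of the lower list is handling or stress of the wild type panicles. It cannot be told apart from an effect of the knockdown with a single wild type pool.

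The OsMADS2 probe differed little for the target of a knockdown. Compression by the background step is argued against as the whole cause, since the lowest log2 value under any alternative was -0.59. That value is from the authors' ratios, which were not centred. It was -0.42 in those ratios after centring and -0.32 with offset 0. The probe may also read the transcript of the RNA interference construct, which was not tested, as no probe sequence was used here.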
